A study of Mus musculus with 4 samples.

How the data were processed

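Single-cell RNA sequencing (10x Genomics Chromium, in which each droplet tags the RNA of a cell with a barcode and each RNA molecule with a unique molecular identifier, UMI) was made from pleural fluid cells of mice carrying Lewis lung carcinoma (LLC) malignant pleural effusions. There were 4 libraries, 1 per treatment, and each library was a pool of cells from 3 mice. The deposited values are counts: each matrix holds whole-number UMI counts per gene and barcode, made with Cell Ranger 3.0.2 per the file headers, with no normalization, and it still contains the barcodes of near-empty droplets. The submitters' processing notes also name Cell Ranger, without a version, and the mm10 build. The labels give both version 2 and version 3 of the 3' reagent kit in different places, and the version used was not settled here. Red blood cells had been lysed before the cells were loaded, per the labels, and 4000 cells were loaded for each condition. The 4 matrices share 27998 genes, named by the gene symbols in the deposited gene table. Gene coordinates were read from the annotation of GRCm38, the assembly that mm10 names.

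A barcode was kept when its UMI total reached the lowest point of the smoothed density of log10 UMI of its own library between 300 and 5000 UMIs, when it had at least 200 detected genes and when at most 10% of its UMIs came from mitochondrially encoded (mt-) genes. The UMI minimum came to 944 for PBS, 923 for LNP-cGAMP, 944 for anti-PD-L1 and 1109 for the combination. At that minimum 3077, 3931, 3472 and 3691 barcodes were found in the same order, and the mt- limit removed 240, 84, 67 and 167 of them. Scrublet, run per library with its automatic threshold, called 2, 4, 2 and 5 doublets, at most 0.142% of cells. That is under 0.5%, so the caller is treated as not having worked, and doublets remain in the data. Cells kept numbered 2831 (PBS), 3837 (LNP-cGAMP), 3387 (anti-PD-L1) and 3517 (combination).

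All kept cells were clustered together with scanpy 1.11.5 on log-transformed counts per 10000, using 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1 (leidenalg 0.10.2, igraph 0.11.9). Interferon response, MHC class I, proliferation, heat-shock, haemoglobin, mt-, ribosomal-protein, immunoglobulin and T cell receptor variable, Xist and Y-linked genes were left out of the variable genes. Clusters were named from marker genes, and names are given as "-like". A cluster whose leading genes went against its name, or whose cells had few UMIs and no marker of that name among the 10 leading genes, stayed unnamed. Monocyte-like and macrophage-like clusters were merged into 1 class, and both kinds of conventional dendritic cell into another, after the clusters had been seen. A class was compared between libraries if it held at least 50 cells in each, which left 3 classes: monocyte/macrophage-like, neutrophil-like and T cell-like.

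Within each class the UMI counts of all cells of a library were summed per gene and divided by the sum over all genes, and this share is given on the CPM scale. Genes with at least 20 UMIs over the libraries and 50 CPM in at least 1 of them entered, which gave 3275 genes for monocyte/macrophage-like, 2651 for neutrophil-like and 3347 for T cell-like cells. Log2 ratios were taken as log2 of (CPM + 10) over (CPM + 10), so that genes of low CPM give ratios nearer to 0, whereas folds are plain ratios of CPM. Intervals of a CPM or fold are exact 95% Poisson intervals (for a ratio, from the conditional binomial), and intervals of a share are exact 95% Clopper-Pearson intervals. All of them cover counting error only. With 1 library per treatment there is no replicate, so no test was run, no p-value is given and no difference between libraries has a replicate check. Where a count was 0, the limit given is that of 3 counts. The annotation held coordinates for all 196 genes looked up.

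The design gives 5 comparisons: each treatment against PBS, and the combination against each agent alone. For each of 32 gene lists the median log2 ratio of its measured genes was taken. Its 95% interval came from 1000 resamplings of the genes and their counts, and its percentile came from 10000 random lists of equal size matched on mean CPM in 20 bins, as a description of these libraries. A member is counted as higher or lower when its log2 ratio amounts to at least 1.5-fold. All lists were computed in every class; those described were picked after their values and a wider run of the alternatives had been seen. The myeloid chemokine list in neutrophil-like cells, whose direction turned under several settings, was at that point left out and then put back.

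Named genes followed a rule. For each agent over its pair of comparisons, which share no library, and for the combination against PBS, the 5 genes with the highest and the 3 with the lowest log2 ratio in each class were named (for an agent, by the smaller in size of its log2 ratios, with equal sign in both). Ribosomal-protein, mt-, haemoglobin, immunoglobulin, T cell receptor, Xist, Y-linked and clone-named genes were left out of that ranking. Also named are a panel of 30 genes whatever their values, up to 4 members with the highest mean CPM of each list described, and markers that name a cluster. The groups, the filters on cells and genes, the clustering, the markers, the lists, the named-gene rule and 16 of the alternatives were set before the data were examined.

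Cells were called female when they had a UMI of Xist, the transcript that silences 1 X chromosome in female cells, and none of 4 Y-linked genes (Ddx3y, Eif2s3y, Kdm5d, Uty), and male in the opposite case. These calls were added after the data had been seen. In another step added then, monocyte/macrophage-like clusters were assigned to the PBS side or the LNP-cGAMP side if their share of cells differed at least 10-fold between these libraries, and were otherwise called shared.

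The alternatives set beforehand changed the UMI minimum (2 settings), the mt- limit (20%), the treatment of doublets, the variable genes, the clustering resolution (0.5 and 2), the naming of classes (marker scores per cell), the scaling (TMM and median-of-ratios factors), the pseudocount (1 CPM), the gene filter, the weighting of cells and of clusters, the depth (cells thinned to 500 UMIs) and the background (subtraction of the profile of barcodes with 10 to 100 UMIs). For that subtraction the background share was estimated from markers of other classes. The estimator was changed from their median to their 10% quantile after the median had given implausibly large shares. The equal weighting of clusters took only clusters with at least 20 cells in both libraries of a comparison. Thinning gives every cell the same 500 UMIs, so it also weights cells equally. There were 5 alternatives added after the data had been seen: subtraction of the profile and amount of the near-empty barcodes of each library, leaving out the 3% of cells with the highest Scrublet scores, male-called cells alone, female-called cells alone, and 1 cluster of each class alone.

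The ratios, intervals and list percentiles were tested on simulated sums with 200 genes changed by known folds for LNP-cGAMP against PBS. The counts were drawn as Poisson from the PBS profile, which is the model the intervals assume. The outcome therefore checks the computation and not the spread between mice or cells. Filtering, clustering and naming were not simulated. In monocyte/macrophage-like cells (3275 genes) 100% of the genes changed 2-fold had an interval that excluded 1 in the right direction, and 94.9% of unchanged genes had an interval that held 1. In neutrophil-like cells (2651 genes) these values were 100% and 96.0%, and in T cell-like cells (3347 genes) 100% and 96.1%. Of 100 simulated lists without change, 91%, 85% and 91% had a percentile between 5 and 95 in the 3 classes in this order. Computations used Python 3.11.15, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9.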

Results

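Malignant pleural effusions were raised in C57BL/6 mice with LLC, a mouse lung carcinoma line, and treated by injection into the pleural cavity on day 11. The treatments were PBS, LNP-cGAMP (1 µg), an anti-PD-L1 antibody (30 µg) or both agents together. LNP-cGAMP is a nanoparticle form of cGAMP, the cyclic dinucleotide that activates STING, an adaptor that switches on interferon genes. Anti-PD-L1 blocks a ligand that restrains T cells. Pleural fluid cells were collected on day 13, 48 h after treatment, and pooled from 3 mice for each of the 4 libraries. The layout asks how the cells of the effusion differed with each agent alone and with their combination. Each group is 1 library, so the values below describe these libraries and no difference has a replicate check.

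The libraries held 86269137 (PBS), 68828158 (LNP-cGAMP), 87696440 (anti-PD-L1) and 88855120 (combination) UMIs over all barcodes. After filtering, 2831, 3837, 3387 and 3517 cells remained in this order, with a median of 17193, 16405, 17636 and 18719 UMIs per cell. The pools differed in the sex of their mice as read from the cells. Of the cells with a sex call, 0.0532% were female in PBS and 0% in LNP-cGAMP (upper 95% limit 0.137%). In anti-PD-L1 the share was 67.8% and in the combination 78.4%. LNP-cGAMP against PBS therefore compares cells of male mice, and the other comparisons set mixed pools against male or mixed pools. Neither mark was found in 910 (PBS), 1124 (LNP-cGAMP), 917 (anti-PD-L1) and 1115 (combination) cells, tumour cell-like cells left out.

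Monocyte/macrophage-like cells were the largest class in every library, at 57.4% of cells in PBS (95% interval 55.6 to 59.3), 59.9% in LNP-cGAMP (58.3 to 61.4), 60.6% in anti-PD-L1 (58.9 to 62.2) and 72.4% in the combination (70.9 to 73.8). Neutrophil-like cells, named by genes such as S100a9 and Retnlg, made up 30.5% (28.8 to 32.3), 28.1% (26.7 to 29.6), 27.2% (25.7 to 28.7) and 16.6% (15.4 to 17.9) in the same order. T cell-like cells, which carried Cd3g, Cd3e and Cd8a or Il7r and Tcf7, stood at 2.83% (2.25 to 3.505) in PBS, 6.12% (5.39 to 6.93) in LNP-cGAMP, 4.16% (3.52 to 4.89) in anti-PD-L1 and 4.44% (3.78 to 5.17) in the combination. NK cell-like cells, led by Gzma and Ncr1, were at 2.74% (2.24 to 3.30) in LNP-cGAMP and between 0.995% and 1.15% elsewhere. Conventional dendritic cell-like cells, led by MHC class II genes, were at 3.99% (3.30 to 4.78) in PBS, 1.25% (0.924 to 1.66) in LNP-cGAMP, 3.19% (2.62 to 3.84) in anti-PD-L1 and 2.08% (1.63 to 2.603) in the combination. LLC tumour cell-like cells, led by Cald1 and Hmga2, held 1.31%, 0.469%, 0.974% and 0.682%. The 18 such cells of LNP-cGAMP had a median of 1261 UMIs, against 71407 in PBS.

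Neutrophil shares depend on the UMI minimum, which was 944 in PBS, 923 in LNP-cGAMP, 944 in anti-PD-L1 and 1109 in the combination. The median neutrophil-like cell held 2096, 2407, 2285 and 2519 UMIs. A minimum of 0.1 of the 99th percentile of the top 4000 barcodes was 8679, 5988, 8460 and 7832 UMIs in the same order. With it neutrophil-like cells came to 0.632%, 1.91%, 1.124% and 0.499%. Since it lies above the median neutrophil-like cell, most of the class was bound to be lost, and these shares cannot be compared between libraries. At a clustering resolution of 2 the neutrophil-like cells of LNP-cGAMP came to 17.8%. At resolution 0.5 monocyte/macrophage-like cells of PBS came to 34.7%, and T cell-like cells to 0.565% in PBS and 1.59% in anti-PD-L1.

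**Figure D1:**
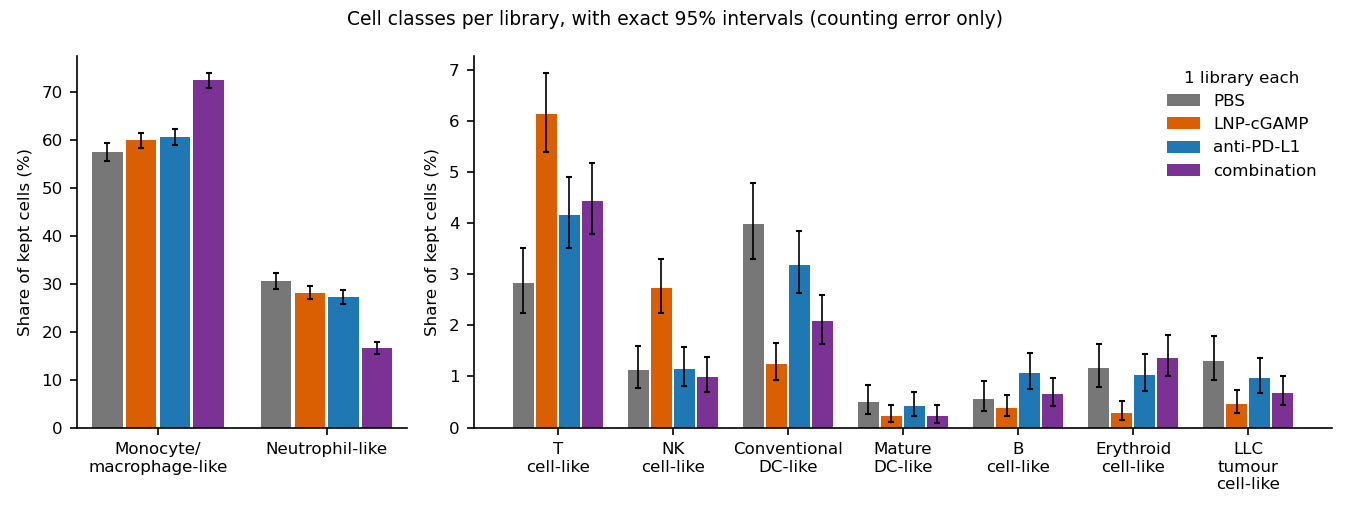
Share of kept cells (%) in each named class for the 4 libraries (bars, 1 library each), with exact 95% intervals as error bars that cover counting error only. Neutrophil-like cells were at 16.6% in the combination against 27.2% to 30.5% elsewhere, and T cell-like cells at 6.12% in LNP-cGAMP against 2.83% in PBS.

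Interferon-stimulated genes stood higher in the monocyte/macrophage-like cells of LNP-cGAMP than in those of PBS. Of the 31 measured genes of the type I interferon response, 29 were at least 1.5-fold higher and 0 were lower, with a median log2 ratio of 1.06 (95% interval 0.81 to 1.42) at the 100th percentile of the matched lists. Irf7, a transcription factor that amplifies interferon production, was at 1126 CPM against 243 (4.63-fold, 4.55 to 4.72). Isg15, an interferon-induced ubiquitin-like protein (ENSMUSG00000035692, GRCm38 chromosome 4, 156199424 to 156200818), was 3.98-fold higher (3.89 to 4.06). Ifit1 stood at 145 against 39.0 CPM and Ifi27l2a at 2119 against 659. Tmem173, the gene of STING, was at 145 against 75.3 CPM. Transcripts of Ifnb1, the interferon gene itself, were too few to compare at this depth, with 1 UMI in LNP-cGAMP and 0 in PBS. Of 18 interferon-gamma response genes 8 were higher and 0 lower (median 0.49, 0.08 to 0.82), while the abundant members Gbp2 (808 against 1166 CPM), Iigp1 (453 against 542) and Irf8 (354 against 353) were not.

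Antigen presentation genes parted by class. Of 16 MHC class I presentation genes, 11 were higher and 0 lower in LNP-cGAMP (median 0.76, 0.28 to 1.29), among them H2-K1 at 4768 against 1975 CPM, H2-D1 at 5542 against 3192 and B2m at 3960 against 2354. H2-Q6 (ENSMUSG00000073409, GRCm38 chromosome 17, 35424850 to 35430055) was 21.3-fold (19.5 to 23.2) and H2-Q7 8.51-fold (8.22 to 8.82) higher. These neighbouring genes are similar in sequence, so the split of counts between them is uncertain. Of 7 MHC class II presentation genes, 0 were higher and 5 lower (median -0.87, -1.02 to -0.32). H2-Ab1 stood at 183 against 343 CPM, H2-Aa at 213 against 438 and Cd74, the invariant chain, at 822 against 1528. In cluster 5 alone this median was -2.30.

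Ccl5, a chemokine that attracts T cells (ENSMUSG00000035042, GRCm38 chromosome 11, 83525778 to 83530518), stood at 771 CPM in LNP-cGAMP against 5.24 in PBS (147-fold, 132 to 165). Cxcl10, another T cell chemokine, was at 212 against 62.1 CPM, whereas Cxcl9 was at 15.5 against 19.3, Ccl4 at 343 against 378 and Ccl3 at 97.4 against 85.9. Of the 5 measured T and NK cell-recruiting chemokines 3 were higher and 0 lower (median 0.60, -0.13 to 5.66). Of 9 myeloid-recruiting chemokines 4 were higher and 2 lower (median 0.55, 0.14 to 1.22; -0.43 in cluster 5 alone), with Ccl8 at 1987 against 933 CPM, Ccl2 at 1670 against 1139, Ccl6 at 9321 against 15384 and Ccl24 at 19.5 against 181. Saa3, an acute-phase protein, was at 6967 against 407 CPM (17.1-fold, 16.9 to 17.3), the collagenase Mmp8 at 201 against 8.72 (23.1-fold, 21.1 to 25.2) and the secreted phosphoprotein Spp1 at 952 against 159 (5.98-fold, 5.85 to 6.12). Among panel genes, Tnf stood at 14.8 against 7.09 CPM, Il1b at 34.3 against 50.3, Il6 at 0.833 against 0.676, Il12b at 0.0595 against 0.169, Vegfa at 2.06 against 3.94 and Fcgr4 at 1094 against 1030. Cd274, the gene of PD-L1, was at 174 against 123 CPM, Cd86 at 39.2 against 31.8 and Cd40 at 29.7 against 38.1.

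Genes of macrophage states differed in both directions. Of 9 inflammatory monocyte genes, 7 were higher and 1 lower in LNP-cGAMP (median 1.11, -0.04 to 2.17; 0.42 with each cell weighted equally). They include Ly6c2 at 1184 against 88.9 CPM (13.3-fold, 12.9 to 13.7), Ms4a4c at 955 against 210 and Plac8 at 1900 against 1214. Of 6 classically activated (M1) genes 4 were higher and 0 lower (median 0.80), with the Fc receptor gene Fcgr1 at 1055 against 538 CPM. The panel gene Nos2, which makes nitric oxide, was at 13.1 against 2.47. Of 10 alternatively activated (M2) genes 2 were higher and 5 lower (median -0.61, -1.54 to 0.54). Arg1, the arginase of these cells, was 2.68-fold lower (1774 against 4764 CPM) and the mannose receptor gene Mrc1 2.20-fold lower. Of 7 resident pleural macrophage genes 1 was higher and 4 lower (median -0.84; -0.0017 in cluster 5 alone), with Lyve1 11.9-fold and Cd5l 2.22-fold lower. The scavenger receptor gene Marco was 16.8-fold lower and Fn1, fibronectin, 7.93-fold lower. Of 7 proliferation genes 0 were higher and 6 lower (median -1.47; -0.24 in cluster 5 alone), with Stmn1 8.92-fold and Tubb5 3.22-fold lower.

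Different clusters held this class in the libraries. In PBS 660 and 560 of 1626 cells lay in clusters 1 (led by Cd163 and Ccl24) and 4 (Lyve1, Marco), and in LNP-cGAMP 842 and 733 of 2298 lay in clusters 2 (Ms4a7, Ccl12) and 6 (Saa3). Cluster 5 (Vcan, Ccr2) held 307 and 195, and within it alone the log2 ratios were 0.72 for Ccl5, 2.42 for Saa3, 1.17 for Mmp8 and -0.39 for Marco. The mt- transcripts differed beside these groups: 0 of 10 were higher and 9 lower in LNP-cGAMP (median -1.81, -2.08 to -1.24; -0.79 in cluster 5), with mt-Co3 at 2028 against 7094 CPM. The median mt- share per cell was 1.06% against 3.32% at 20600 against 34738 UMIs. The 14 housekeeping genes had a median of -0.22 (-0.48 to 0.08).

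Interferon genes also stood higher in the neutrophil-like cells of LNP-cGAMP than of PBS. Of 35 type I interferon genes, 22 were higher and 0 lower (median 0.74, 0.52 to 1.38). Ifit1bl1 (ENSMUSG00000079339, GRCm38 chromosome 19, 34592891 to 34601956) was at 286 against 8.80 CPM (32.5-fold, 20.2 to 56.1), Pyhin1 at 296 against 21.2 and Ifit3 at 1448 against 213. Ifi27l2a was 6.45-fold, Irf7 2.97-fold, Ifit1 2.83-fold and Isg15 1.82-fold higher. H2-Q6 was 19.2-fold (13.1 to 29.4), H2-Q7 10.1-fold and H2-K1 2.11-fold higher, and of 16 MHC class I presentation genes 7 were higher and 0 lower (median 0.36, and -0.12 at clustering resolution 2). Of 13 granule and maturation genes 7 were higher and 2 lower (median 0.71, 0.30 to 2.57). Retnlg, a marker of mature neutrophils, stood at 14725 against 5111 CPM, the iron-binding Lcn2 at 3836 against 1562, and the granule proteases Mmp8 at 2188 against 281 and Mmp9 at 1325 against 2281. In cluster 3 alone that median was -0.10. Saa3, which monocyte/macrophage-like cells hold at 6967 against 407 CPM, was counted at 607 against 74.6 CPM, where the estimated share of background RNA was 4.36% and 7.01%.

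Of 13 hypoxia and glycolysis genes 0 were higher and 6 lower in these neutrophil-like cells (median -0.56), with Pkm at 1493 against 2444 CPM, Eno1 at 542 against 686 and Ldha at 473 against 636. Of 8 myeloid-recruiting chemokines 0 were higher and 4 lower (median -0.61, -1.16 to -0.40), with Cxcl2, which draws neutrophils, at 847 against 2138 CPM and Cxcl3 at 111 against 313. That median was 0.35 with the RNA of near-empty barcodes subtracted and 0.08 with classes from marker scores. Subtracting the profile of barcodes with 10 to 100 UMIs moved it the other way, to -1.32. The lowest genes by the ranking were Slc20a1, a phosphate transporter (3.43-fold lower), Mir142hg (2.91-fold) and Rgs3 (2.06-fold, and 0.13 on the log2 scale in cluster 3 alone). Cd274 was at 423 against 371 CPM (log2 -0.46 at resolution 2) and Il1b at 3613 against 4698 (0.23 in cluster 3 alone). Red cell RNA was lower: the 4 haemoglobin genes had a median of -4.42, with Hbb-bs 185-fold lower than its 980 CPM in PBS, and male-called cells alone gave -0.15. The last value rests on 286 cells in LNP-cGAMP and 229 in PBS. Both pools were male by their calls, so it cannot be read as a difference between sexes. Of 10 mt- genes 0 were higher and 7 lower (median -0.88). Clusters 3, 7 and 8 held 451, 330 and 298 of these cells in LNP-cGAMP and 280, 185 and 399 in PBS. The median of all 2651 genes was -0.15 here, and TMM scaling moves every log2 ratio by 0.26.

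Among T cell-like cells the cytotoxic genes stood higher in LNP-cGAMP (235 cells, median 17139 UMIs) than in PBS (80 cells, median 5835 UMIs). Of 17 cytotoxic effector genes 10 were higher and 1 lower (median 0.67, 0.43 to 1.39; 1.51 with each cell weighted equally). Gzmb (ENSMUSG00000015437, GRCm38 chromosome 14, 56258838 to 56262260) was at 5480 against 1095 CPM (5.00-fold, 4.69 to 5.34), and its product granzyme B kills target cells. Gzma was at 1343 against 464, Gzmk at 153 against 43.6, Nkg7 at 2442 against 1297, Ccl5 at 3929 against 2819 and Ccl3 at 371 against 79.4. Prf1, perforin, stood at 164 against 79.4 CPM and Ifng at 91.8 against 50.3, whereas Gzmf was at 25.5 against 197. Of 19 proliferation genes 9 were higher and 0 lower (median 0.56; 1.62 with each cell weighted equally), among them Hmgb2, Tubb5, Stmn1 and Ube2c at 1.61-fold to 1.74-fold. Of 9 naive and memory genes 0 were higher and 9 lower (median -1.29), with Il7r at 73.3 against 218 CPM, Klf2 at 303 against 533 and Satb1 at 75.1 against 175. Foxp3, the regulator of regulatory T cells, was at 4.36 against 38.0 CPM, and of 7 regulatory T cell genes 1 was higher and 3 lower (median -0.49). Checkpoint receptor genes gave 1 higher and 0 lower of 8 (median 0.03; 0.97 with each cell weighted equally, 0.95 with cells thinned to 500 UMIs and -0.32 in cluster 13 alone), with Pdcd1, the gene of PD-1, at 320 against 304 and Lag3 at 243 against 200 (log2 -0.39 in that cluster). Thinning also weights cells equally, so its value and that of equal weighting are not separate checks.

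Type I interferon genes of the T cell-like cells gave a median of 0.34 (-0.03 to 0.69; 7 of 20 higher, 1 lower), with Ifi27l2a at 1341 against 514 CPM, Bst2 at 338 against 169, Irf7 at 198 against 120, Isg15 at 176 against 144, Ifi47 at 337 against 407 and Ifit1 at 52.5 against 72.7 (log2 0.11 in cluster 13 alone). Transcripts of other cell types differed between the libraries as well. Of 8 MHC class II genes 0 were higher and 7 lower (median -2.34; 1.32 in cluster 13 alone), with Cd74 at 427 against 2351 CPM and H2-Ab1 at 128 against 775. S100a8 was at 163 against 763, S100a9 at 182 against 957, and Saa3 at 432 against 10.1. The mt- median was -0.47. Cluster 12 (Gzmb, Cd8a) held 158 of 235 cells in LNP-cGAMP and 16 of 80 in PBS, and cluster 13 (Il7r, Tcf7) held the rest. Over all libraries the median cell held 26257 UMIs in cluster 12 and 5825 in cluster 13. The few cluster 12 cells of PBS thus weigh more in its class sum than their number, which intervals of counting error do not cover. T cell-like cells had a median of 7472 UMIs in anti-PD-L1 and 17298 in the combination. Within cluster 13 alone the log2 ratio was 0.48 for Gzmb, -0.03 for Prf1 and -0.35 for Ifng, and the naive and memory median was -0.24. The median of all 3347 genes was 0.12.

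**Figure D2:**
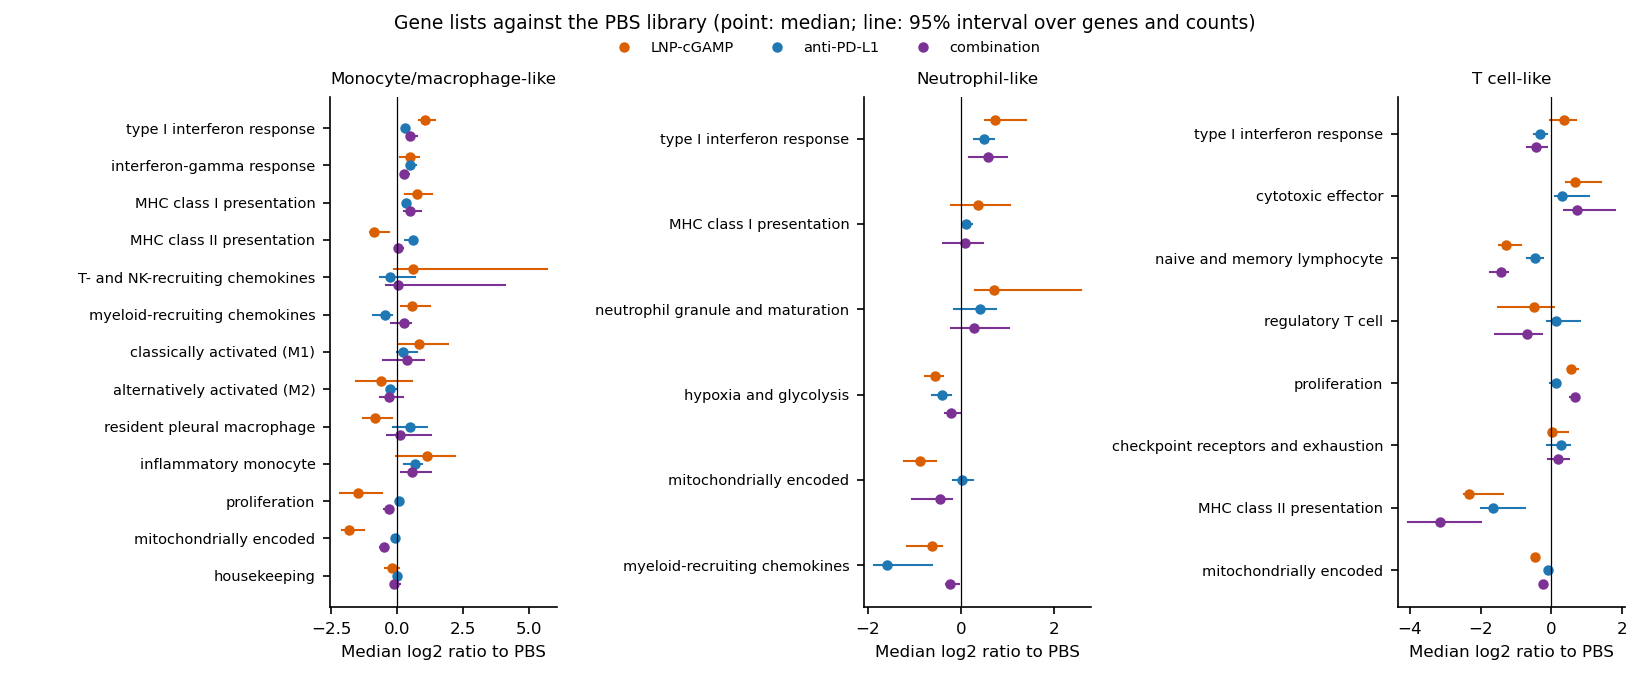
Median log2 ratio to PBS of the measured genes of each list (points; x axis) in 3 cell classes, with lines for 95% intervals over genes and counts; colours give the library. In monocyte/macrophage-like cells the type I interferon median was 1.06 in LNP-cGAMP, 0.31 in anti-PD-L1 and 0.50 in the combination, and the mt- median -1.81, -0.11 and -0.51.

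With the antibody alone, monocyte/macrophage-like cells differed from PBS in fewer genes of these lists. Of 31 type I interferon genes 2 were higher and 0 lower (median 0.31, 0.24 to 0.42; 0.17 in male-called cells alone). Isg15 stood at 291 against 183 CPM (1.59-fold, 1.55 to 1.63), Irf7 at 360 against 243 and Cxcl10 at 105 against 62.1 (log2 -0.088 in cluster 5 alone). Of 18 interferon-gamma response genes 6 were higher and 0 lower (median 0.47, 0.35 to 0.69), with the guanylate-binding protein genes Gbp2b at 311 against 133 CPM and Gbp2 at 1598 against 1166. MHC class II presentation was higher in 4 of 7 genes and lower in 0 (median 0.59, 0.28 to 0.65), with Cd74 at 2370 against 1528, H2-Aa at 652 against 438, H2-Ab1 at 522 against 343 and H2-DMb1 at 211 against 122. For MHC class I presentation 2 of 16 were higher (median 0.33), with H2-K1 at 2337 against 1975. Cd274 was at 191 against 123 CPM, Fcgr4 at 1313 against 1030, Nos2 at 7.98 against 2.47 and Il15ra at 67.6 against 33.3.

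Alox15, a lipoxygenase of resident peritoneal and pleural macrophages (ENSMUSG00000018924, GRCm38 chromosome 11, 70344152 to 70352031), was at 242 against 55.1 CPM (4.40-fold, 4.24 to 4.57), Prg4 at 110 against 44.8 and Serpinb2 at 59.3 against 24.4. These genes also lead cluster 14, which held 98 of 2051 cells in anti-PD-L1 and 33 of 1626 in PBS. Male-called cells alone gave log2 ratios of -1.07, -0.49 and -0.66 for the 3 genes, and -0.75 for the resident pleural macrophage list, whose median over all cells was 0.47 (-0.16 to 1.14; 3 of 7 higher, 0 lower). Lower in anti-PD-L1 were Apoe, a lipid carrier (1416 against 2994 CPM, and -0.13 in male-called cells alone), the small heat-shock gene Hspb1 (7.73 against 38.8) and Cxcl3 (3.38-fold lower). Of 9 inflammatory monocyte genes 5 were higher and 0 lower (median 0.68), with Ly6c2 at 334 against 88.9 CPM and Chil3 at 1476 against 762. Of 9 myeloid-recruiting chemokines 0 were higher and 4 lower (median -0.47), with Ccl8 at 615 against 933, Ccl2 at 818 against 1139 and Ccl24 at 89.4 against 181. For the 5 T and NK cell-recruiting chemokines the median was -0.27 (1 higher, 1 lower; 0.12 in male-called cells), with Ccl5 at 7.60 against 5.24 CPM (log2 -0.15 in cluster 5 alone). Medians of M1 (0.23), M2 (-0.26), proliferation (0.07; -0.14 in male-called cells), mt- (-0.11) and housekeeping (-0.02) genes lay nearer to 0. Clusters 1, 4 and 5 held 638, 588 and 597 of these cells.

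Neutrophil-like cells of anti-PD-L1 had 14 of 35 type I interferon genes higher and 0 lower (median 0.48, 0.29 to 0.72), and male-called cells alone gave 0.08. Ifit3 stood at 798 against 213 CPM, Ifi27l2a at 1730 against 715, Irf7 at 959 against 493, Isg15 at 2966 against 1757 and Ifitm1, an interferon-induced membrane protein, at 16389 against 11332. Upp1, uridine phosphorylase, was at 1465 against 756 CPM, Ly6a at 848 against 540, Tnfrsf18 at 56.3 against 31.1 and Mapk13 at 204 against 117. Of these Upp1, Ly6a and Tnfrsf18 turned in male-called cells alone (log2 -0.26, -0.87 and -0.86). That setting rests on 78 of 921 neutrophil-like cells in anti-PD-L1 and 229 of 864 in PBS. Since 719 and 634 cells had no call, it selects cells by detected transcripts as well as by sex. Ptgs2, the inducible cyclooxygenase, was at 19.5 against 72.5, Hist2h2aa1 at 10.6 against 50.2 and Chil3 at 709 against 1543 CPM (log2 0.57 in male-called cells). All 8 myeloid-recruiting chemokines were lower (median -1.59, -1.86 to -0.62; -0.29 with near-empty RNA subtracted), with Ccl9 at 95.3 against 336 and Cxcl3 at 89.6 against 313. Granule genes gave 4 higher and 3 lower of 13 (median 0.41; -0.18 in cluster 3 alone), hypoxia and glycolysis genes 0 higher and 3 lower (median -0.41), MHC class I genes 1 higher of 16 (median 0.10; -0.13 in male-called cells), mt- genes a median of 0.02 and haemoglobin genes -4.46 (-0.12 in male-called cells). The median of all genes was -0.15, and TMM scaling adds 0.25.

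T cell-like cells of anti-PD-L1 held more transcripts of the granzyme genes Gzmf, at 1350 against 197 CPM (6.85-fold, 5.88 to 8.03), and Gzme, at 171 CPM (153-fold, 27.2 to 6048, from 1 UMI in PBS). Gzmb was at 2665 against 1095 CPM and the chemokine gene Xcl1 at 78.6 against 4.48, while Gzma was at 195 against 464. Of 17 cytotoxic genes 7 were higher and 1 lower (median 0.29; 1.21 with cells thinned to 500 UMIs). Serpine2 stood at 150 against 90.6 CPM (log2 -0.35 in cluster 13 alone), Ctla4 at 178 against 90.6, Pdcd1 at 350 against 304 (log2 -0.27 with cells thinned), and the X-linked gene Eif2s3x at 73.6 against 45.9, beside the difference in sex. Type I interferon genes gave 1 higher and 4 lower of 20 (median -0.33), with Isg15 at 76.7 against 144 (log2 0.16 with cells thinned) and Ifit1 at 25.6 against 72.7. The naive and memory median was -0.45 (1 higher, 3 lower of 9), regulatory T cell genes gave 0.12 (-0.29 with each cell weighted equally), checkpoint genes 0.27 and proliferation genes 0.14 (1.501 in cluster 13 alone). MHC class II genes had a median of -1.65 (0 of 8 higher, 7 lower; 1.59 in cluster 13 alone), S100a9 was at 145 against 957 CPM (log2 1.26 with classes from marker scores), and the mt- median was -0.09. Clusters 12 and 13 held 52 and 89 of these cells.

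In the combination, monocyte/macrophage-like cells stood between PBS and LNP-cGAMP in most of these lists. Of 31 type I interferon genes 14 were higher than in PBS and 0 lower (median 0.50, 0.40 to 0.75), with Irf7 at 624 against 243 CPM (2.57-fold, 2.52 to 2.62), Isg15 at 397 against 183 (2.17-fold, 2.12 to 2.22), Ifit1 at 75.9 against 39.0 and Ifi27l2a at 1991 against 659. Male-called cells alone gave a median of -0.25, and log2 ratios of -0.67 for Isg15, -0.63 for Ifit1 and -1.51 for Cxcl10, which over all cells was at 81.0 against 62.1 CPM. Ccl5 stood at 251 against 5.24 CPM (48.0-fold, 42.9 to 53.9), Saa3 at 5329 against 407 (13.1-fold, 12.9 to 13.3), H2-Q6 at 98.2 against 9.02 and Ly6c2 at 753 against 88.9. Marco (3.11-fold lower), Ccl24 (4.84-fold) and Fn1 (2.74-fold) were the lowest by the ranking. MHC class I presentation was higher in 7 of 16 genes (median 0.47), with H2-K1 at 3740 against 1975 CPM. MHC class II presentation had a median of 0.04 (0 of 7 higher or lower; -1.30 in male-called cells alone). Interferon-gamma response genes gave 3 higher and 1 lower of 18 (median 0.26; -0.93 in male-called cells).

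Further lists of the combination against PBS lay nearer to 0 than those of LNP-cGAMP. Arg1 was at 3423 against 4764 CPM, Mrc1 at 331 against 451, Lyve1 at 329 against 457 and Il1b at 14.9 against 50.3. Medians were 0.36 for M1 genes (2 of 6 higher, 1 lower; -0.056 in cluster 5 alone), -0.32 for M2 genes (1 higher, 3 lower of 10), 0.11 for resident macrophage genes (0.84 in male-called cells, -0.21 at resolution 0.5 and -0.17 with clusters weighted equally, which kept no cluster of the LNP-cGAMP side), 0.55 for inflammatory monocyte genes (4 higher, 1 lower of 9) and -0.31 for proliferation genes (0 higher, 1 lower of 7; -1.07 in male-called cells). They were 0.25 for myeloid-recruiting chemokines (2 higher, 1 lower of 9; -0.28 in male-called cells), 0.03 for T and NK cell-recruiting chemokines (1 of 5 higher; -0.49 in cluster 5 alone), -0.51 for mt- genes (0 higher, 4 lower of 10) and -0.14 for housekeeping genes. Cd274 stood at 150 against 123 CPM and Tmem173 at 112 against 75.3 (log2 -1.16 and -0.71 in male-called cells alone), Nos2 at 9.46 against 2.47 and Tnf at 7.73 against 7.09. Of the 2545 cells, 721 lay in cluster 2, 354 in cluster 4, 318 in cluster 6, 316 in cluster 5 and 284 in cluster 1.

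**Figure D3:**
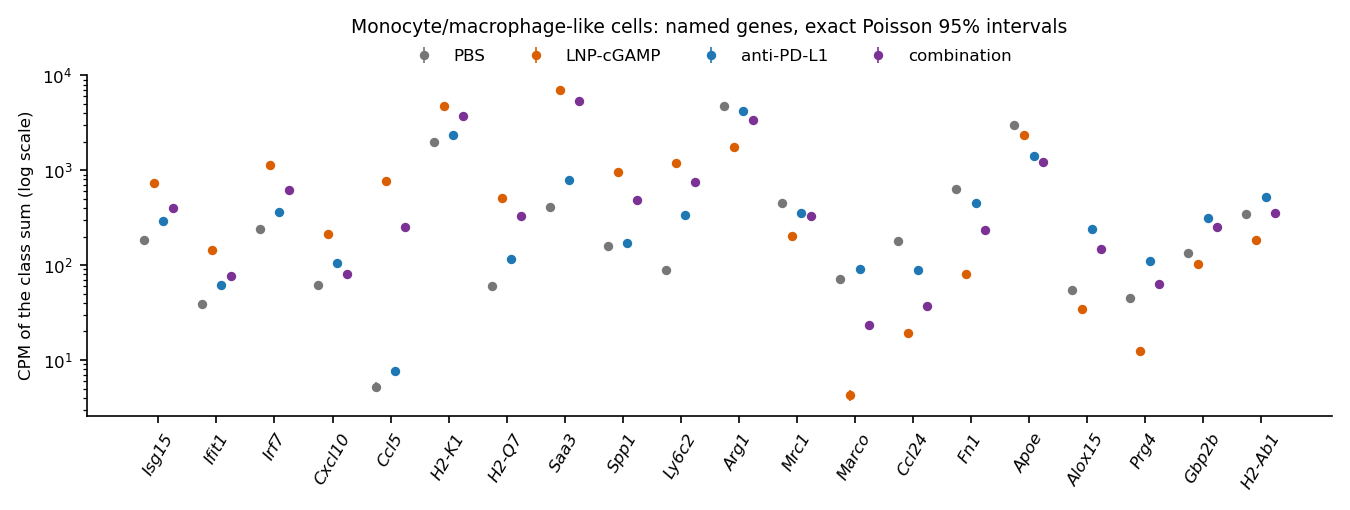
CPM of named genes (log10 axis) in monocyte/macrophage-like cells of the 4 libraries (colours, 1 library each), with exact 95% Poisson intervals that are mostly smaller than the points. Ccl5 stood at 5.24 in PBS, 771 in LNP-cGAMP, 7.60 in anti-PD-L1 and 251 in the combination, and Marco at 71.7, 4.26, 91.7 and 23.1.

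Neutrophil-like cells of the combination had 16 of 35 type I interferon genes higher than in PBS and 0 lower (median 0.58, 0.17 to 0.99). Ifit1bl1 was 14.9-fold higher (9.05 to 26.0), Pyhin1 7.30-fold, Ifi27l2a 5.13-fold and Ifit3 4.73-fold. Retnlg stood at 10580 against 5111 CPM and Mmp8 at 1212 against 281, and granule genes gave 5 higher and 3 lower of 13 (median 0.27). Lower by the ranking were Chil3 at 460 against 1543 CPM, Rgs3 at 40.5 against 149 and Bhlhe40, a transcription factor, 4.23-fold lower. Cd274 was at 276 against 371. Hypoxia and glycolysis genes had a median of -0.21 (0 higher, 2 lower of 13) and myeloid-recruiting chemokines of -0.23 (0 of 8 higher or lower). TMM scaling turned them to 0.10 and 0.09: the median of all genes was -0.25, and this scaling adds 0.33. The MHC class I median was 0.09 (-0.12 at resolution 2), the mt- median -0.46 and the haemoglobin median -4.56, with 0 UMIs of Hba-a1, below the limit of 1.96 CPM that 3 counts give, against 286 CPM in PBS; its reads are shared with a near-identical copy. Clusters 3, 7 and 8 held 367, 173 and 45 of these cells.

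T cell-like cells of the combination had 12 of 17 cytotoxic genes higher than in PBS and 1 lower (median 0.72; 1.51 with each cell weighted equally). Gzmb stood at 5220 against 1095 CPM (4.77-fold, 4.47 to 5.09), Gzma at 1251 against 464, Ccl3 at 542 against 79.4, Ifng at 222 against 50.3 (4.41-fold, 3.26 to 6.09), Xcl1 at 168 against 4.48 (37.6-fold, 14.6 to 139), Mt3, a metallothionein, at 64.3 against 6.71, and Prf1 at 137 against 79.4. In cluster 13 alone the log2 ratio was -0.94 for Gzmb and -0.35 for Ifng. All 9 naive and memory genes were lower (median -1.43; -0.10 in cluster 13 alone), and proliferation genes gave 12 higher and 0 lower of 19 (median 0.66; 1.68 with each cell weighted equally). Foxp3 was at 0.287 against 38.0 CPM, from 1 UMI in the combination (fold 0.00754, 0.000186 to 0.0450), and the regulatory T cell median was -0.69 (-1.29 in cluster 13 alone). Checkpoint genes had a median of 0.19 (0.81 with each cell weighted equally, -0.50 in cluster 13 alone), with Pdcd1 at 325 against 304. Type I interferon genes gave 1 higher and 7 lower of 20 (median -0.44), with Isg15 at 88.4 against 144 (log2 0.03 with cells thinned). The MHC class II median was -3.15 (0 of 8 higher, 8 lower; 0.95 in cluster 13 alone), S100a9 was at 44.5 against 957 CPM, Saa3 at 536 against 10.1, and the mt- median was -0.25. Clusters 12 and 13 held 106 and 50 of these cells, and TMM scaling moves every log2 ratio by 0.11.

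The combination and LNP-cGAMP alone differ by the antibody and by the mice pooled: of the monocyte/macrophage-like cells with a sex call 76.3% were female in the combination and 0% in LNP-cGAMP. In this class 13 of 31 type I interferon genes were lower in the combination and 0 higher (median -0.52, -0.65 to -0.42; -1.27 in male-called cells alone), with Irf7 at 624 against 1126 CPM, Isg15 at 397 against 727 and Cxcl10 at 81.0 against 212. Of 7 MHC class II genes 6 were higher (median 0.88, 0.59 to 0.97), while male-called cells alone gave -0.46 and clusters weighted equally 0.17. The equal weighting kept no cluster of the PBS side in this comparison. Alox15 stood at 146 against 34.2, Prg4 at 63.6 against 12.4, Gbp2b at 251 against 104 and H2-DMb1 at 143 against 74.7 CPM, the last pair with log2 ratios of -1.55 and -0.68 in male-called cells. Apoe was at 1225 against 2356 CPM (log2 0.03 in male-called cells) and Hspb1 at 24.9 against 94.6. Medians were 0.96 for resident macrophage genes, 0.91 for proliferation genes (0.02 in cluster 5 alone, 0.32 in male-called cells alone and 0.30 with clusters weighted equally), 1.29 for mt- genes (0.39 in cluster 5 alone), -0.27 for MHC class I genes and -0.65 for inflammatory monocyte genes. In neutrophil-like cells the type I interferon median was -0.38, the granule median -0.48 (0.09 in cluster 3 alone) and the myeloid-recruiting chemokine median 0.46, with -0.12 after subtraction of near-empty RNA. In T cell-like cells 12 of 20 type I interferon genes were lower (median -0.70), the cytotoxic median was -0.01, and Ifng stood at 222 against 91.8 CPM and Xcl1 at 168 against 6.91 (log2 -0.50 in cluster 13 alone).

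The combination and the antibody alone differ by LNP-cGAMP and by the mice pooled. Of the monocyte/macrophage-like cells with a sex call 76.3% and 67.4% were female. In monocyte/macrophage-like cells 5 of 31 type I interferon genes were higher and 0 lower (median 0.23, 0.13 to 0.39), with 0.26 in female-called and -0.47 in male-called cells alone. Ccl5 stood at 251 against 7.60 CPM, Saa3 at 5329 against 799, Spp1 at 489 against 172 and H2-Q6 was 4.47-fold higher, while Marco was at 23.1 against 91.7 (log2 0.04 in female-called cells) and Gbp2 at 772 against 1598. The MHC class II median was -0.53 (0 of 7 higher, 2 lower; -1.85 in male-called and -0.34 in female-called cells alone), the mt- median -0.44 and the MHC class I median 0.21 (-0.01 in male-called cells). In neutrophil-like cells the type I interferon median was -0.02 and the myeloid-recruiting chemokine median 1.46 (0.21 with the profile of barcodes of 10 to 100 UMIs subtracted), and Mmp8 was at 1212 against 403 CPM. In T cell-like cells the naive and memory median was -1.02 (0.15 in cluster 13 alone) and the cytotoxic median 0.43. Gzma stood at 1251 against 195 CPM (log2 -1.87 in cluster 13 alone), Gzmk at 137 against 41.1 and Ifi27l2a at 1079 against 474, and Gzmf at 118 against 1350.

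Each agent was present in a pair of comparisons that share no library, and the log2 ratios of LNP-cGAMP went together more closely than those of the antibody. Across the 3275 genes of monocyte/macrophage-like cells, which are not independent replicates, LNP-cGAMP against PBS and the combination against anti-PD-L1 had Pearson r = 0.753 (0.496 in male-called cells alone, 0.498 in cluster 5 alone), with 92 genes at least 1.5-fold in both in the same direction and 3 in opposite directions. Ccl5, Saa3, H2-Q6, Mmp8 and Spp1 led the genes higher in both, and Marco, Ccl24 and Fn1 those lower in both. In the combination against anti-PD-L1, male-called cells alone gave 0.43 on the log2 scale for Fn1, and female-called cells alone gave 0.040 for Marco. For the antibody the same measure was r = -0.000895 (-0.272 in male-called cells alone), with 15 genes in the same and 21 in opposite directions. In neutrophil-like cells r was 0.244 for LNP-cGAMP (74 and 31 genes; 0.392 with near-empty RNA subtracted) and -0.0983 for the antibody (23 and 39; 0.025 with that subtraction). In T cell-like cells r was 0.541 for LNP-cGAMP (163 and 28 genes; -0.22 in cluster 13 alone) and 0.141 for the antibody (28 and 34; -0.305 in cluster 13 alone).

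Per cell, the UMIs of the type I interferon list in 10000 had a median of 43.1 in the monocyte/macrophage-like cells of PBS, 100.4 in LNP-cGAMP, 56.6 in anti-PD-L1 and 75.5 in the combination. The middle 50% of cells of the combination lay between 49.9 and 111.0, against 77.4 and 130.6 in LNP-cGAMP.

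**Figure D4:**
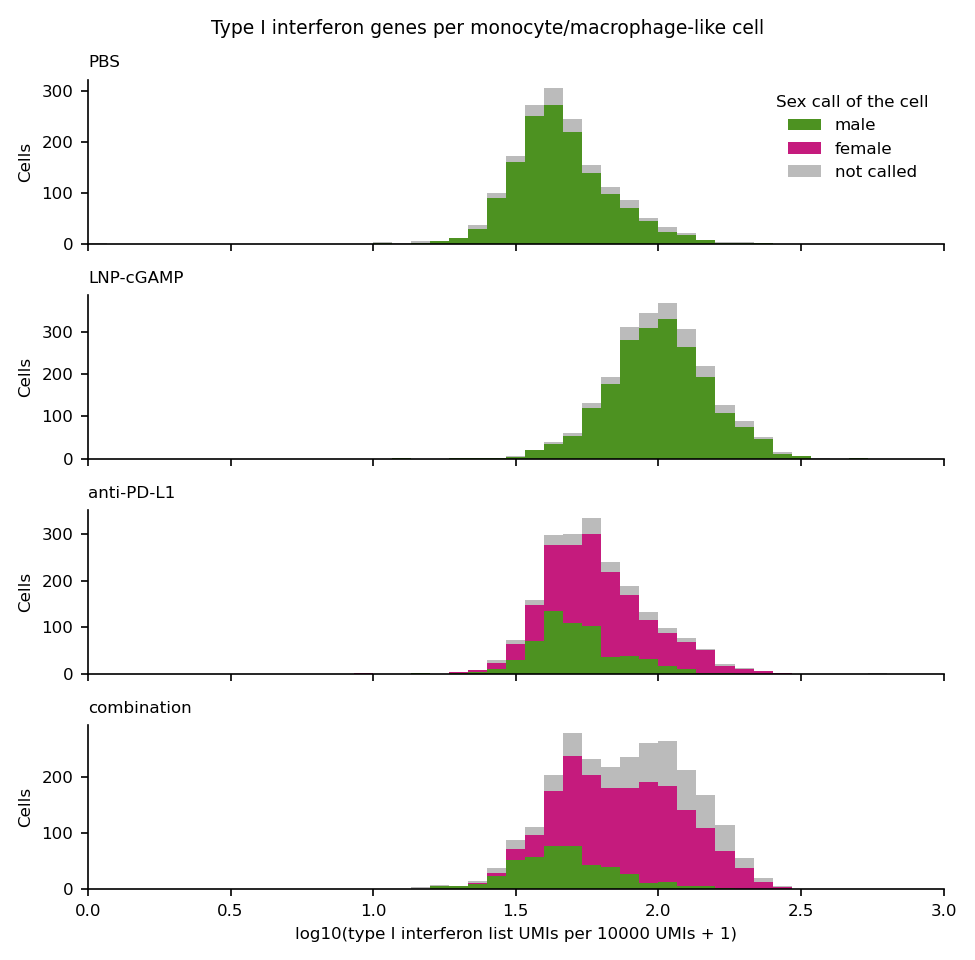
Number of monocyte/macrophage-like cells (y axis) by log10 of their type I interferon list UMIs per 10000 UMIs plus 1 (x axis), 1 panel per library, stacked by the sex call of the cell. The medians before the logarithm were 43.1 in PBS, 100.4 in LNP-cGAMP, 56.6 in anti-PD-L1 and 75.5 in the combination.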

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

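All tests of explanations in this part were chosen after the results had been seen, and none of the differences between cell classes or sexes listed here was tested. Signal in data that the comparisons do not use came from Xist, a gene of female cells: monocyte/macrophage-like cells held 226 CPM in anti-PD-L1 and 237 CPM in the combination, against 0.101 in PBS and 0.0198 in LNP-cGAMP.

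Several lists went opposite ways in different cell classes under the same comparison, in part only under some settings. Type I interferon genes in anti-PD-L1 against PBS had medians of 0.31 in monocyte/macrophage-like (0.17 in male-called cells alone), 0.48 in neutrophil-like (0.084 in male-called cells alone) and -0.33 in T cell-like cells, and in the combination against PBS 0.50 (-0.25 in male-called cells alone), 0.58 and -0.44. The T cell-like medians rest on 80 cells in PBS, 16 of them in cluster 12. With cells thinned to 500 UMIs the member Isg15 turned to 0.16 and 0.032 in these comparisons. The T cell-like list medians are not among the values that turned direction. MHC class II genes in anti-PD-L1 against PBS stood at 0.59 in monocyte/macrophage-like and -1.65 in T cell-like cells, where cluster 13 alone gave 1.59 and so no opposite sign. Proliferation genes stood at -1.47 and 0.56 in these classes for LNP-cGAMP, and at -0.31 and 0.66 for the combination. Myeloid-recruiting chemokines of LNP-cGAMP stood at 0.55 in monocyte/macrophage-like cells (-0.43 in cluster 5 alone) and -0.61 in neutrophil-like cells (0.35 with near-empty RNA subtracted, 0.079 with classes from marker scores). In the neutrophil-like cells, subtracting the profile of barcodes with 10 to 100 UMIs gave -1.32. Between sexes, the type I interferon median of the combination against anti-PD-L1 was -0.47 in male-called and 0.26 in female-called monocyte/macrophage-like cells, and the resident macrophage median was 1.58 (1.02 to 3.72) and -0.73 (-1.66 to 0.0023).

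In the combination, 710 of 2545 monocyte/macrophage-like cells lay in clusters of the PBS side and 1398 in clusters of the LNP-cGAMP side. Of the cells with a sex call, 39.0% were male-called on the LNP-cGAMP side (36.0 to 42.1) and 1.27% on the PBS side (0.551 to 2.49). The calls cover 606 female and 388 male of the 1398 cells on the LNP-cGAMP side, and 621 and 8 of the 710 on the PBS side. Over the class 508 cells had neither mark and 86 had both, and the sex mix of these is not known. Cells of other libraries read through shared barcodes do not account for it, since 0.423% of the PBS-side cells had a barcode also found in PBS or anti-PD-L1 cells. That the pooled mice differed in their state fits the unequal sex shares and stays open, because sex marks mice here and could also act by itself. Beyond this comparison of sex shares no biological explanation was tested, the treatments included.

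The type I interferon difference of anti-PD-L1 against PBS in monocyte/macrophage-like cells, at 0.31, was 0.17 in male-called cells alone. The mix of mice, as marked by sex, may therefore hold part of it, while a part remains between male-called cells. Subtracting a share of free RNA estimated from markers of other cells, 1.05% in PBS and 4.65% in anti-PD-L1, gave 0.32. An estimate from near-empty barcodes ranked the libraries the other way, at 0.511% and 0.0927%. With that amount subtracted, as in every setting except male-called cells alone, the median was at least 0.28. Free RNA, as the whole cause, is thus argued against only at these estimates, which disagree in size and order. The antibody itself and other differences between the mice stay open as untested.

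The mt- genes of monocyte/macrophage-like cells stood lower in LNP-cGAMP than in PBS, at -1.81. An equal loss of mt- transcripts in the whole library, as the whole cause, is argued against by -0.47 in the T cell-like cells, and by -0.42 in their cluster 13 alone. A part stays open, since the mt- share was lower in LNP-cGAMP in every class tabulated: 1.15% against 3.06% in conventional dendritic cell-like, 4.05% against 5.07% in NK cell-like and 0.501% against 0.777% in neutrophil-like cells. Within cluster 5 alone the median was -0.79, so the different clusters that hold the class are not the whole cause, although they could hold a part. The depth per cell, 20600 against 34738 UMIs, stays open, since thinning to 500 UMIs gave -1.67 but keeps the mt- proportion of each cell on average, and the treatment stays open as untested.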

How the results depend on the processing

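The settings on 1 cluster alone, on male-called and on female-called cells, on near-empty RNA and on the highest Scrublet scores were chosen after the results had been seen, and the other 16 were planned. Over 390 results these 21 alternatives gave 7164 values: 5417 stayed within the interval of the reported value, 1659 lay outside it with no called turn of direction, and 88 turned direction. No paired analysis was possible because the results come from no test, with 1 library per group. For the values listed here the cause was not tested. The type I interferon median of monocyte/macrophage-like cells in LNP-cGAMP against PBS kept its direction under 20 alternatives, from 0.95 to 1.21. In anti-PD-L1 against PBS it ran from 0.17 to 0.46. In the combination it ran from -0.25 to 0.64 against PBS, and from 0.40 to 0.64 without the male-called setting. The minimum of 0.1 of the 99th percentile left too few neutrophil-like and T cell-like cells for gene values, and resolution 0.5 gave 279 of 390 values. Depth limits the neutrophil-like cells, at a median of 2096 UMIs in PBS.

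With that higher minimum the monocyte/macrophage-like share was 74.0% in PBS, 77.6% in LNP-cGAMP, 72.7% in anti-PD-L1 and 78.5% in the combination, the neutrophil-like share 0.632%, 1.91%, 1.124% and 0.499%, and the T cell-like share 0.976% in PBS and 2.43% in anti-PD-L1. This minimum ran from 5988 UMIs in LNP-cGAMP to 8679 in PBS, above the median neutrophil-like cell, so the neutrophil-like shares cannot be compared between libraries. Resolution 0.5 gave monocyte/macrophage-like shares of 34.7% in PBS, 42.7% in anti-PD-L1 and 64.8% in the combination, and T cell-like shares of 0.565%, 4.12%, 1.59% and 3.07% in the order above. Marker scores per cell gave 47.8%, 46.1%, 49.3% and 58.3% for monocyte/macrophage-like cells, and 27.6% (PBS) and 25.5% (anti-PD-L1) for neutrophil-like cells. Neutrophil-like shares of LNP-cGAMP, anti-PD-L1 and the combination were 17.4%, 23.9% and 11.5% with all variable genes, and 17.8%, 25.3% and 12.1% at resolution 2.

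In male-called monocyte/macrophage-like cells alone the type I interferon median was 0.17 in anti-PD-L1 against PBS, -0.25 in the combination against PBS, -1.27 against LNP-cGAMP and -0.47 against anti-PD-L1. The interferon-gamma median of the combination against PBS was -0.93, with Isg15 at -0.67 and Ifit1 at -0.63, and the MHC class II median against LNP-cGAMP was -0.46, with Gbp2b at -1.55, H2-DMb1 at -0.68 and Apoe at 0.032. Fn1 was at 0.43 in the combination against anti-PD-L1. In anti-PD-L1 against PBS Alox15 was at -1.07, Prg4 at -0.49 and Serpinb2 at -0.66, and in neutrophil-like cells the MHC class I median was -0.13, Upp1 -0.26, Tnfrsf18 -0.86, Ly6a -0.87 and Chil3 0.57. The neutrophil-like values rest on 78 male-called cells in anti-PD-L1 and 229 in PBS. The r across genes in monocyte/macrophage-like cells was 0.496 for LNP-cGAMP and -0.272 for the antibody. Female-called cells of the combination against anti-PD-L1 gave 0.040 for Marco, and 0.024 for H2-Aa in T cell-like cells.

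Cluster 5 held 0 female-called cells in PBS and LNP-cGAMP, 376 in anti-PD-L1 and 232 in the combination. In that cluster alone, LNP-cGAMP against PBS gave a myeloid-recruiting chemokine median of -0.43, anti-PD-L1 against PBS gave -1.08 for Serpinb2 and -0.088 for Cxcl10, the combination gave 0.62 for Apoe and 1.37 for Cxcl3 against LNP-cGAMP and a proliferation median of 0.10 against anti-PD-L1, and r for LNP-cGAMP was 0.498. In neutrophil-like cluster 3 the granule median was -0.10 in LNP-cGAMP against PBS and 0.088 in the combination against LNP-cGAMP, and Rgs3 was at 0.13 in the former. Weighting clusters equally gave monocyte/macrophage-like type I interferon medians of 0.40 in the combination against PBS and 0.10 against anti-PD-L1. Against LNP-cGAMP it gave -0.0088 for Gbp2b, -0.35 for Serpinb2 and 0.035 for Cxcl3, and r for LNP-cGAMP was 0.522. The equal weighting of the combination against PBS left out all clusters of the LNP-cGAMP side (kept: 1, 4, 5, 14 and 15). Against LNP-cGAMP it left out all of the PBS side (kept: 2, 5, 6, 9, 10 and 14). The comparison with anti-PD-L1 rested on clusters 1, 2, 4, 5, 14 and 15, and that of LNP-cGAMP with PBS, which enters r, on 5 and 14.

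For T cell-like cells against PBS the equal weighting rests on cluster 13 only, so it equals the setting on that cluster alone. There the MHC class II genes turned to medians of 1.32 (LNP-cGAMP), 1.59 (anti-PD-L1) and 0.95 (combination) against PBS, with Cd74 at 1.38 in LNP-cGAMP and 0.90 in the combination, and H2-Aa at 1.58, 2.10 and 1.46. It also gave -0.94 for Gzmb and -0.35 for Ifng in the combination, -0.35 for Ifng and -0.027 for Prf1 in LNP-cGAMP, and -0.35 for Serpine2 in anti-PD-L1. The naive and memory median of the combination against anti-PD-L1 was 0.093 with equal weights and 0.15 in cluster 13, and r for LNP-cGAMP was -0.0338 and -0.223. Cluster 13 alone further gave, in the combination against anti-PD-L1, a proliferation median of -1.16, an mt- median of 0.021 and -1.87 for Gzma, and -0.50 for Xcl1 against LNP-cGAMP.

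Thinning cells to 500 UMIs also weights them equally, so it is not a check of depth alone. It gave a type I interferon median of 0.46 for monocyte/macrophage-like cells of anti-PD-L1 and r = 0.603 for LNP-cGAMP. In T cell-like cells it turned Serpine2 to -0.21 (anti-PD-L1 against PBS) and -1.13 (combination against LNP-cGAMP), Isg15 to 0.16 in anti-PD-L1 and 0.032 in the combination, and Ifng to -0.29 in LNP-cGAMP. The myeloid-recruiting chemokine median of neutrophil-like cells turned to 0.079 with marker scores and 0.35 with near-empty RNA subtracted in LNP-cGAMP, and in the combination against PBS to 0.19 and 0.24 with these settings, 0.085 with TMM and 0.11 with median-of-ratios factors. In the combination against LNP-cGAMP this median was -0.12 with near-empty RNA and -0.059 with the profile of 10 to 100 UMIs subtracted. That profile moved it to -1.32 in LNP-cGAMP against PBS, opposite to near-empty RNA. The hypoxia and glycolysis median of the combination against PBS was 0.10 with TMM and 0.12 with median-of-ratios factors, since these add to every log2 ratio there. Marker scores turned S100a9 to 1.26 and S100a8 to 1.90 in T cell-like cells of anti-PD-L1. The MHC class II median of T cell-like cells in the combination against LNP-cGAMP was 0.20 with all variable genes, 0.13 with a minimum of 1000 UMIs and 0.0082 with called doublets kept, and H2-Aa was at 0.059 and 0.051 under the former pair.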

Other observations

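The monocyte/macrophage-like cells of the combination were split into sides and sexes after the data had been seen. The sides are groups of expression clusters, so differences between them follow in part from the clustering, and genes that lead any of these clusters are left out of that comparison. In female-called cells of the LNP-cGAMP side (606 cells) Isg15 stood at 702 CPM, Cxcl10 at 142, Cd274 at 231, H2-K1 at 5104 and Tmem173 at 192. In those of the PBS side (621 cells) they stood at 184, 44.5, 143, 2650 and 84.5, and the MHC class II genes H2-Ab1 at 464 against 194 and Cd74 at 1941 against 969. Male-called cells of the LNP-cGAMP side (388 cells) had Ccl5 at 446 CPM, against 274 in the female-called cells of that side. Their Isg15 was at 112 CPM, Cxcl10 at 14.6 and Cd274 at 50.9, and their median of type I interferon list UMIs in 10000 was 45.6 against 105.7.

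In monocyte/macrophage-like cells of LNP-cGAMP against PBS, 5 of 7 apoptosis and p53 genes were at least 1.5-fold higher and 0 lower (median 0.68, 0.51 to 1.33). Of 10 dissociation and heat-shock genes 5 were higher and 0 lower, and the other 5 lay within 1.5-fold (median 0.53, 0.10 to 0.73). In anti-PD-L1 these medians were -0.03 and -0.11. In T cell-like cells the interferon-gamma response genes of the combination gave 0 higher and 7 lower of 13 against PBS (median -0.65). In neutrophil-like cells the median of type I interferon list UMIs in 10000 was 113.9 in PBS, 267.9 in LNP-cGAMP, 174.5 in anti-PD-L1 and 189.2 in the combination, and in T cell-like cells 35.1, 42.3, 23.8 and 30.4.

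Cluster 5 (Vcan, Ccr2) held cells of every library, and its median of type I interferon list UMIs in 10000 was 69.2 in PBS, 184 in LNP-cGAMP, 90.3 in anti-PD-L1 and 133 in the combination. Its cells with a sex call also differed: 0 were female and 247 male in PBS, 0 and 171 in LNP-cGAMP, 376 and 148 in anti-PD-L1, and 232 and 5 in the combination. The share of its cells below the anti-PD-L1 median was 74.9% in PBS, 3.59% in LNP-cGAMP and 22.5% in the combination. The libraries shared 14 to 20 barcodes of kept cells by pair. An even draw from the whole barcode list of the matrices would give 1.41 to 1.99. Whether the cells drew evenly on that whole list is not known, and the kit version was not settled. These counts therefore cannot show an excess over chance.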
